A study of Homo sapiens with 4 samples.

How the data were processed

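RNA levels were measured with Clariom S Human arrays in KGN cells, a human granulosa cell line that came from a granulosa cell tumour. Cells had received control siRNA (siNC, 10 nM) or siRNAs against YAP and TAZ (siYT, 5 nM each). After 48 h the medium was replaced with medium that held 0.5 mM 8Br-cAMP, a cell-permeable analogue of cyclic AMP, or none, for 24 h more. Total RNA was labelled with biotin and hybridised, and each of the 4 groups was represented by 1 array. The siRNA sequences were not given in the sources used here.

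The deposited values are log2 signals that the authors computed with RMA in the Affymetrix Expression Console, per the labels. RMA corrects the background, gives the arrays a shared distribution and summarises the probes of each probe set. The software versions and the genome build of the probe annotation were not given in the sources used here. The deposited log2 values ran from 1.39 to 19.36. Values above 16, the log2 of the maximum of a 16-bit scanner, are not scanner brightness, so a further rescaling that the labels do not name is possible. Levels are therefore given in deposited log2 units, and folds are computed from those units. If the values were rescaled, such a fold need not be a ratio of signals. No coordinates are given.

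The table held 24351 probe sets. Of these, 17709 named exactly 1 gene and gave 17687 genes, after the probe sets of the 20 genes with several were averaged. No gene was named for 3739 transcript clusters and 2903 probe sets were controls, and both kinds were kept apart from the comparisons. XIST and Y-linked genes were left out of the named genes. Array medians over all probe sets lay between 6.20 and 6.27.

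Each comparison is a difference of log2 values between 2 arrays. A gene was called by size alone when it differed by at least 1, which is 2-fold, and its higher value reached the level filter of 6.22, the median of all gene-named values over the 4 arrays. The siRNA difference was taken without and with 8Br-cAMP, and the 8Br-cAMP difference after each siRNA. Genes that differed by at least 1 in the same direction in both cases were counted separately, as called in both media or after both siRNAs. For these the highest of the 4 arrays had to reach the level filter. Such a gene can therefore lie under the filter in 1 of the cases. HSD3B2 did so without 8Br-cAMP, at 4.17 in siNC and 5.80 in siYT. The difference of differences is the 8Br-cAMP difference after siYT minus that after siNC, and it equals the siRNA difference with 8Br-cAMP minus that without. It was called by the same size and level rule. With 1 array per group no difference had a replicate check, and no p-value was attached to these calls. A crossed split set siNC and siYT+8Br-cAMP against the other pair of arrays. It equals the difference of differences divided by 2 with its sign turned, so it holds any interaction as well as noise. Where a value lay under the level filter, the size of a difference depends on the background.

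An additive model with siRNA and 8Br-cAMP as its terms was fitted with limma 3.58.1 in R 4.3.3 to all 17687 genes. It has 1 residual degree of freedom, 9.24 prior degrees of freedom and a median moderated standard deviation of 0.314. Its p-values were adjusted by the Benjamini-Hochberg method and called at 0.05. The error of this model contains the difference of differences as well as the noise of the arrays, and it is moderated over all genes. A gene could therefore pass although its 2 differences were far apart. For the siRNA, EDN2 passed with differences of -0.67 without and -4.86 with 8Br-cAMP (limma, adjusted p = 0.0397). This fit across 4 unreplicated arrays is not a test between replicates, so its p-values do not measure the spread between cultures. They are secondary to the sizes. The verbs rose and fell are kept for genes that passed this fit.

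A set of 31 gene lists was fixed before the data were examined, together with the comparisons, thresholds, rule for named genes and all alternatives but 1. The median difference of each list was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called when its median lay under the percentile 2.5 or over the percentile 97.5. Among 31 lists, 1.55 calls per difference are due by chance if the members of a list vary independently. Members that vary together between cultures could give more calls without an effect of the treatment. The percentile ranks a list among other genes of the same arrays and is not a test across replicates. For limma, the count of members adjusted over the list alone is given beside that over all genes.

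The named genes are YAP1 and WWTR1, the 12 highest and 12 lowest genes of each main comparison ranked by the smaller of their 2 differences, and the 8 highest and 8 lowest by the difference of differences. Up to 4 members with the largest mean difference in each list and 18 further genes chosen beforehand were added. AMOTL2, chosen beforehand as well, had no probe set naming it alone.

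The steps were tested on simulated arrays with 200 changed genes and a noise standard deviation of 0.331, the value estimated from the crossed split, which holds interaction as well as noise. Of 17487 unchanged genes, 4 were called in both media, 320 in 1 medium, 6 by limma and 1292 by the difference of differences, a count that follows from how the noise was set. Changed genes were found in both media in 24% of cases at a log2 effect of 1, 74% at 1.5, 98% at 2 and 100% at 3. They were drawn from genes with a mean at least 1 above the level filter, and all genes received the same noise. In the negative controls the crossed split gave 0.735, so these rates and counts do not cover genes near the background. Of 100 random lists without a change, 3 were called, and the simulated noise of their members was independent.

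The alternatives planned were no level filter, a filter at the 75th percentile, thresholds of 1.5-fold and 3-fold, cyclic loess, centring each array on its median, the brightest probe set in place of the mean, and log2 of the linear value plus 32. For limma, fitting only genes past the filter and moderation with trend and robust options were tried. For lists, unmatched random lists, means, members past the filter, and lists without shared members or without the member with the largest difference were tried. A filter at the 95th percentile of the negative controls, which is 6.95, was added after seeing the data. Intervals of medians over genes are 95% bootstrap intervals from 10000 resamples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used beside R.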

Results

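RNA of KGN cells, a human granulosa cell line, was profiled on 4 arrays, 1 for each combination of control siRNA (siNC) or YAP/TAZ siRNA (siYT) with or without 0.5 mM 8Br-cAMP for the last 24 h. Granulosa cells surround the oocyte and make estradiol, and cyclic AMP is the messenger through which gonadotropins act on them. YAP and TAZ are transcriptional coactivators at the end of the Hippo pathway. The values are the deposited log2 signals, and the small number of arrays limits the precision. No group had a replicate, so no difference between 2 arrays could be checked against the spread between cultures. Across probe sets, pairs of arrays correlated with r from 0.942, for siNC and siYT+8Br-cAMP, to 0.977, for siNC and siNC+8Br-cAMP; probe sets are not independent replicates. The 2197 positive control probe sets of the array had a median difference of -0.36 between siYT and siNC without 8Br-cAMP and of -0.35 with it. The 612 negative control probe sets lay under the level filter of 6.22 in 89.7% to 94.0% of cases per array.

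The first comparison asked what YAP/TAZ siRNA changed in each medium. YAP1, which encodes YAP, was at 9.48 in siNC and 6.80 in siYT, 6.44-fold lower, and at 9.46 and 6.29 with 8Br-cAMP, 8.99-fold lower. WWTR1, which encodes TAZ, was at 7.58 and 5.45, 4.39-fold lower, and at 9.13 and 5.35 with 8Br-cAMP, 13.8-fold lower. Both fell in the additive limma model, with a mean difference of -2.93 and an SE of 0.315 for YAP1 (adjusted p = 0.000391) and of -2.96 and an SE of 0.401 for WWTR1 (adjusted p = 0.00144). The siYT values of WWTR1 lay under the level filter, and those of YAP1 under the 95th percentile of the negative controls of their arrays (7.29 without and 6.98 with 8Br-cAMP), so the folds of both genes depend on the background. WWTR1 was 1.55 higher with 8Br-cAMP after siNC and -0.10 different after siYT.

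The classical YAP/TAZ targets were among the genes with the largest decreases. ANKRD1, a muscle and stress response protein, differed by -6.14 on the log2 scale without 8Br-cAMP, from 14.42 to 8.28, and by -9.27 with it, from 13.08 to 3.81. The last value lies near the negative control median of 3.66 on that array, so the size of -9.27 depends on the background. CCN2, a secreted matrix protein also called CTGF, differed by -5.25 and -5.58, and its relative CCN1 by -4.57 and -5.42. These 3 genes fell with adjusted p = 8.46e-05, 5.35e-05 and 7.97e-05. Of the 19 measured members of the YAP/TAZ target signature, 5 were called lower in both media, 0 higher and 14 were not called. Its median was -1.05 without and -0.87 with 8Br-cAMP, at the percentiles 0.01 and 0 of random lists. By limma 7 members fell, and adjusted over the list alone 12 fell and 1 rose. F3, the initiator of coagulation, fell by 2.96 on average, while LATS2, the Hippo kinase, differed by -0.82 and -1.37 and did not pass (adjusted p = 0.0606).

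Among the 20 measured Hippo components and TEAD factors, 3 were called lower in both media, 0 higher and 17 were not called. They were VGLL3 (-2.82 and -1.89), a cofactor of TEAD proteins, the transcription factor TEAD4 (-2.78 and -1.42), and WWC1 (-1.74 and -1.02), an upstream regulator. The list medians of -0.13 and -0.29 were not called. Limma called 4 members lower, and 5 lower and 1 higher adjusted over the list alone. TEAD1 differed by -0.47 and -0.91 and did not pass.

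**Figure D1:**
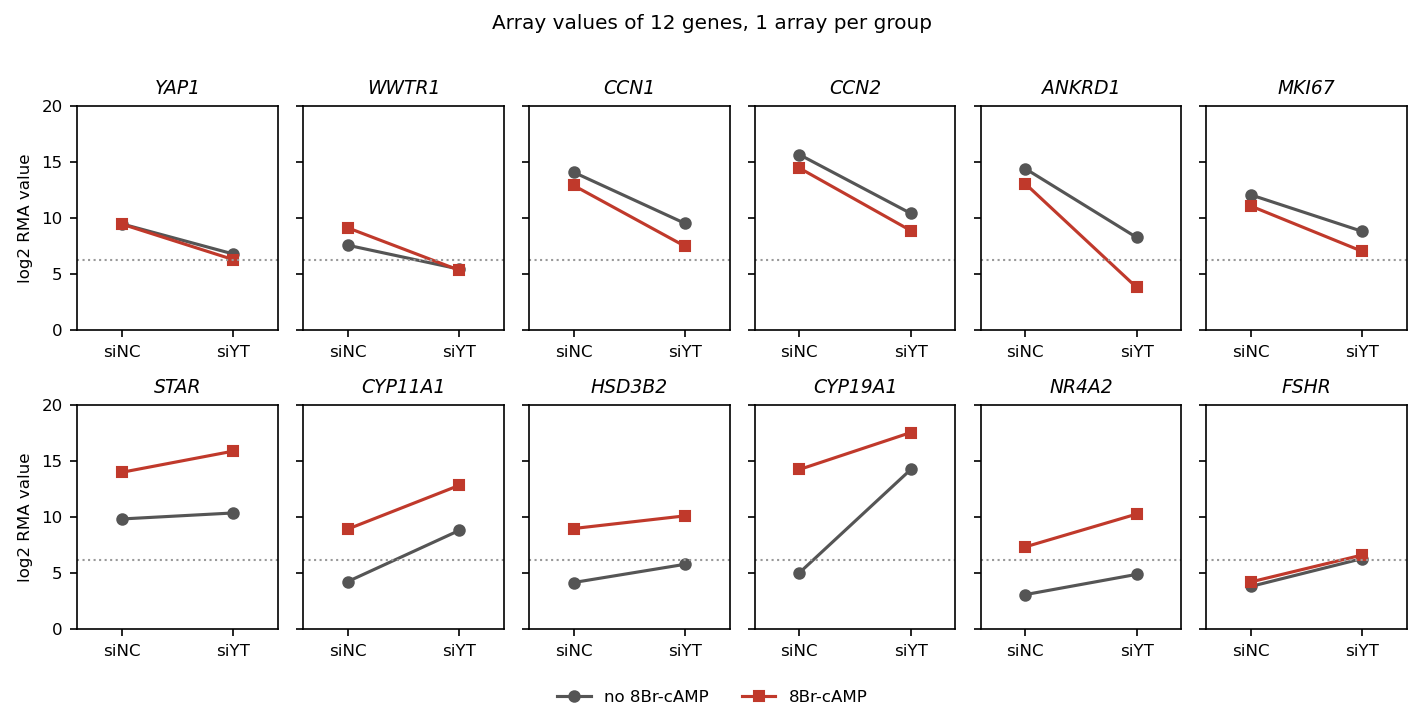
Deposited log2 RMA value (vertical axis, 0 to 20) of 12 genes in siNC and siYT cells without 8Br-cAMP (grey circles) and with it (red squares), 1 array per point and the level filter as a dotted line. YAP1, WWTR1, CCN1, CCN2, ANKRD1 and MKI67 lie lower in siYT, while CYP19A1 rises from 5.04 in siNC to 14.26 in either siYT or siNC+8Br-cAMP and 17.56 in siYT+8Br-cAMP.

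Genes of cell division formed the other large group that was lower after YAP/TAZ siRNA. All 25 mitosis genes were called lower in both media, with medians of -3.59 and -3.84, each at the percentile 0. Limma called all 25 lower, over all genes and adjusted over the list alone. Examples were the cyclins CCNA2 (-4.77 and -4.56) and CCNB2 (-3.90 and -4.202), the kinase TTK (-4.29 and -4.91) and the kinetochore protein NDC80 (-4.60 and -3.999). The proliferation marker MKI67 was at 12.07 in siNC, 8.81 in siYT, 11.07 in siNC+8Br-cAMP and 7.02 in siYT+8Br-cAMP. Of 23 DNA replication genes, 17 were called lower in both media, 0 higher and 6 were not called, with medians of -2.26 and -2.21 at the percentile 0. Limma called 19 of them lower, and all 23 adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, differed by -4.58 and -6.26. TYMS, the thymidylate synthase, differed by -4.33 and -5.64, and CDC6 and CDC45, which load and run the replicative helicase, fell with mean differences of -4.28 and -3.75. PBK, a mitotic kinase, and DLGAP5, a spindle protein, were also among the 12 lowest genes, with -4.68 and -4.86 for PBK and -4.01 and -5.03 for DLGAP5. CDKN1A, the cell cycle inhibitor p21, differed by 0.85 and -0.16. None of the 17 CDK inhibitors and p53 targets was called in both media, and their median was 0.52 (percentile 98.3) without and -0.16 with 8Br-cAMP. TP53INP1, a p53 target, differed by 2.77 and 0.75.

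The remaining genes of the 12 lowest were HMOX1, the heme oxygenase that breaks down heme (-5.76 and -6.09), and KRT18, a keratin (-4.02 and -4.71). Of the 12 lowest, 6 had at least 1 value under the level filter (ANKRD1, HMOX1, PBK, RRM2, TTK and CDC6), so that their sizes and ranks depend on the background.

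Steroid synthesis and matrix genes were prominent among those higher after YAP/TAZ siRNA. CYP19A1, the aromatase that makes estrogens, differed by 9.23, which is 599.7-fold, without 8Br-cAMP and by 3.29, which is 9.81-fold, with it. It rose with a mean of 6.26 and an SE of 0.977 (adjusted p = 0.00321). CYP11A1, which makes pregnenolone from cholesterol, was 4.56 and 3.91 higher. HSD11B1, which makes cortisol from cortisone, was 3.90 and 4.91 higher. HSD3B2, which makes progesterone from pregnenolone, was 1.63 and 1.14 higher. These 3 genes rose with adjusted p = 8.46e-05, 8.46e-05 and 0.0224. The siNC values of CYP19A1, CYP11A1, HSD11B1 and HSD3B2 lay under the level filter, so their folds rest on a level near the background. STAR, which carries cholesterol into mitochondria, differed by 0.54 and 1.89 and did not pass (adjusted p = 0.0738). Of 23 steroid synthesis genes, 5 were called higher in both media, 0 lower and 18 were not called. The median was 0.54 (percentile 99.6) without 8Br-cAMP and 0.28 (percentile 92.4) with it, and limma called 5 higher, or 6 adjusted over the list alone. Averaged over both media the median was 0.29 (percentile 95.6) and not called, while the mean over members of 0.90 (percentile 100) and the median of members past the level filter of 0.596 (percentile 99.56) were called. The 19 genes of cholesterol synthesis and uptake had medians of 0.21 and 0.47, the latter called at the percentile 99.1. Of these, TM7SF2, a sterol reductase, was called higher in both media (1.54 and 1.64), 18 were not called, and limma called 1 higher, or 4 adjusted over the list alone.

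Among 20 granulosa identity genes, 4 were called higher in both media, 1 lower and 15 were not called. Their medians were 0.43 (percentile 98.5) and 0.34 (percentile 95.2). Averaged over both media the median was 0.38 (percentile 98.9), and it was not called without CYP19A1 (percentile 97.4), without members of other lists (percentile 96.5) or with log2 of the linear value plus 32 (percentile 95.4). FSHR, the receptor of follicle-stimulating hormone, was 2.49 and 2.40 higher, with a level that stayed between 3.82 in siNC and 6.63 in siYT+8Br-cAMP. These values lie under the 95th percentile of the negative controls, 6.95, so FSHR is not called with a filter at that level. GJA1, the gap junction protein connexin 43, was 3.64 and 2.31 higher, while FST, the activin antagonist follistatin, was lower by -3.28 and -1.62. Limma called 3 higher and 1 lower, or 5 higher and 2 lower adjusted over the list alone. LHCGR, FOXL2, INHA and HSD17B1, genes of granulosa cells fixed beforehand, stayed under the level filter on all 4 arrays. NR5A1, a regulator of steroid synthesis, differed by 0.64 and 0.55 and did not pass.

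In the extracellular matrix list of 24 genes, 8 were called higher in both media, 1 lower and 15 were not called. Its medians of 1.12 and 0.70 lay at the percentiles 100 and 99.98. LUM, the collagen-binding proteoglycan lumican, was 5.34 and 4.45 higher, DCN, the related decorin, 3.38 and 3.86, and FN1, fibronectin, 3.38 and 2.34. THBS1, thrombospondin, was lower by -3.88 and -3.98. Limma called 8 higher and 1 lower, or 14 higher and 2 lower adjusted over the list alone. LUM and DCN are also the 2 members called higher, with 0 lower and 7 not called, among 9 markers of theca and stromal fibroblasts. The medians of these markers were 0.22 and 0.19 and were not called, and limma called 2 higher, or 3 adjusted over the list alone. For the siRNA difference averaged over both media, the mean over these markers was 1.155 (percentile 99.97) and the median of those past the level filter 1.232 (percentile 99.95), so the list was called under both alternatives. HMCN1, a basement membrane protein (5.78 and 4.62), MGP, an inhibitor of calcification (6.29 and 4.44), and C7, a complement component (4.40 and 3.26), were among the 12 highest genes as well. So were FAIM2, an inhibitor of Fas-induced death (6.96 and 5.25), TMOD1, an actin capping protein (4.31 and 3.79), TMEFF2, a transmembrane protein (4.35 and 3.27), and GBP2, an interferon-induced GTPase (4.06 and 3.28). Of the 12 highest, 8 had at least 1 value under the level filter (FAIM2, LUM, CYP11A1, HSD11B1, DCN, CYP19A1, TMEFF2 and C7), and C7 was at 2.14 in siNC and 3.05 in siNC+8Br-cAMP, so these sizes and ranks depend on the background. C7 reached only 6.53 in siYT and 6.30 in siYT+8Br-cAMP. Both values lie under the filter set from the negative controls, 6.95, so C7 is not called with that filter.

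Signalling lists differed in their direction. Of 21 TGF-beta and BMP genes, 3 were called higher in both media, 2 lower and 16 were not called, with medians of 0.73 (percentile 99.9) and 0.10 (percentile 65.7). Averaged over both media the median was 0.57 (percentile 99.8), and 0.38 (percentile 97.46), which is not called, without the member with the largest difference. The ligands BMP6 (2.48 and 3.94) and TGFB3 (1.15 and 4.18) and LTBP1, which binds latent TGF-beta (1.89 and 2.42), were higher. TGFB3 was at 3.54 in siNC and 4.69 in siYT and BMP6 at 4.71 in siNC, under the level filter. Their sizes without 8Br-cAMP therefore depend on the background. Limma called 5 higher and 2 lower, or 6 and 2 adjusted over the list alone. Of 19 inflammatory cytokines and NF-kB targets, 4 were called lower in both media, 0 higher and 15 were not called, with medians of -0.55 (percentile 0.54) and -0.82 (percentile 0.01). IL6 differed by -2.49 and -7.70, the chemokine CCL20 by -2.81 and -6.48, and CXCL8, interleukin 8, by -2.30 and -4.76. Limma called 1 higher and 4 lower, or 2 and 8 adjusted over the list alone. Of 21 EGF receptor ligand and ERK feedback genes, 2 were called lower in both media, 0 higher and 19 were not called. These were FOSL1, an AP-1 subunit (-3.14 and -2.08), and the receptor ERBB3 (-3.58 and -1.35). The medians were -0.11 and -0.48 (percentile 0.59), and limma called 4 lower, or 5 lower and 1 higher adjusted over the list alone. The 23 interferon response genes had medians of 0.11 without and -1.25 (percentile 0) with 8Br-cAMP. Averaged over both media the median of -0.61 (percentile 0.03) was called and the mean of -0.37 (percentile 3.34) was not. Of them 2 were called higher in both media, 3 lower and 18 were not called, among them BST2 (3.28 and 2.57), a membrane protein that holds back viruses, and IFIT3 (-1.04 and -2.64), an antiviral protein. Limma called 2 higher and 4 lower, or 3 and 9 adjusted over the list alone.

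Over all genes, 2639 were called without 8Br-cAMP, 1345 higher and 1294 lower, and 2028 with it, 977 higher and 1051 lower. In both media, 1297 genes were called in the same direction, 609 higher and 688 lower. Of the 2639 genes, 2406 (91.2%) had the same direction in the other medium, and 20 were at least 2-fold different the opposite way. Across the 9752 genes past the level filter, the differences in the 2 media, which share no array, correlated with r = 0.734 and rho = 0.664; genes are not independent replicates. Limma called 1586 genes, 760 that rose and 826 that fell. With the values as log2 of the linear value plus 32, limma called 0 genes, and 3964 of the 17687 had an unadjusted p under 0.05. The balance of directions depended on scaling: without 8Br-cAMP 1252 were higher and 1376 lower after cyclic loess, and with it 1086 were higher and 963 lower after centring each array.

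**Figure D2:**
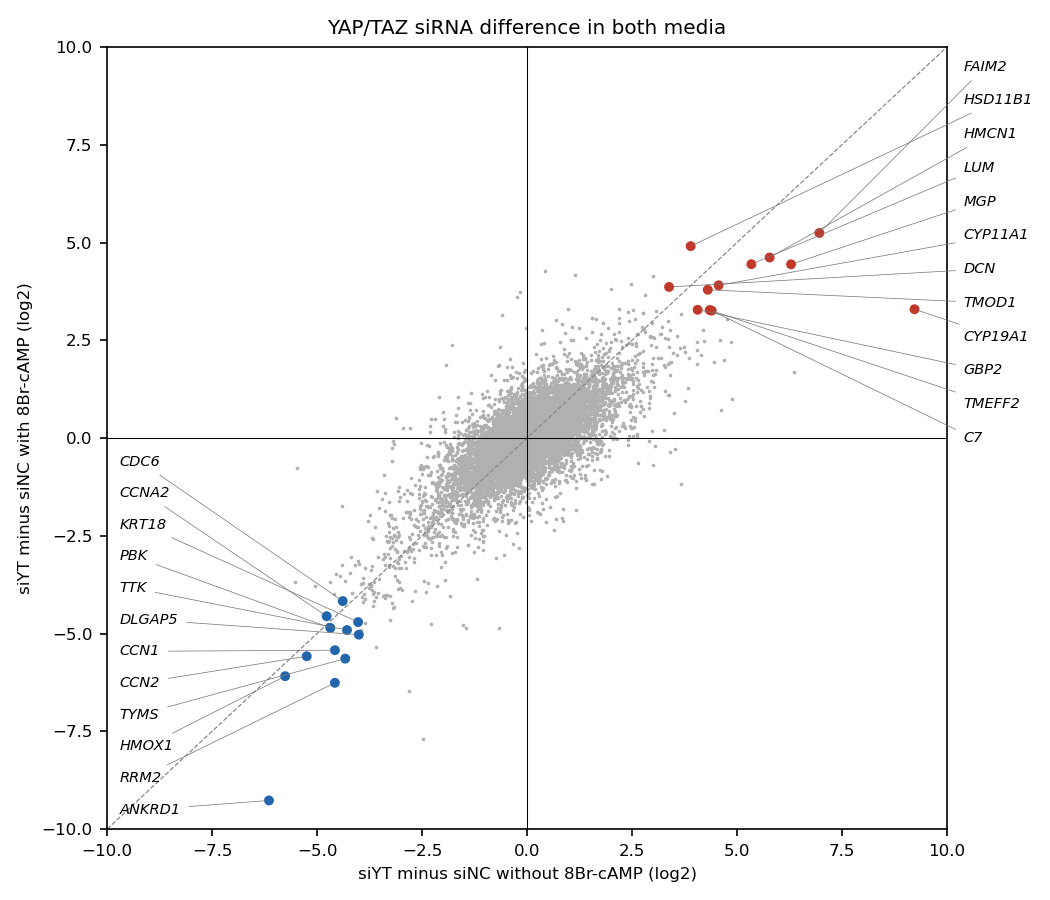
Difference between siYT and siNC on the log2 scale without 8Br-cAMP (horizontal axis) and with it (vertical axis), 1 point per gene past the level filter, with the 12 highest genes by the smaller of both differences in red, the 12 lowest in blue and equality as a dashed line. ANKRD1 lies at -6.14 and -9.27, and CYP19A1 at 9.23 and 3.29.

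The second comparison asked what 8Br-cAMP changed after either siRNA. Genes known to respond to cyclic AMP and genes of steroid synthesis were higher. STAR was at 9.84 without and 14.01 with 8Br-cAMP after siNC, 17.9-fold higher, and at 10.38 and 15.90 after siYT, 45.6-fold higher. CYP11A1 was 25.7-fold and 16.3-fold higher, and HSD3B2 28.3-fold and 20.1-fold higher. CYP19A1 was 599-fold higher after siNC and 9.80-fold higher after siYT. The siNC values of CYP11A1, HSD3B2 and CYP19A1 and the siYT value of HSD3B2 lay under the level filter, so the folds that start from them depend on the background. The folds of STAR, and those of CYP11A1 and CYP19A1 after siYT, start from values above the filter. STAR, CYP11A1, HSD3B2 and CYP19A1 rose in the additive limma model, by 4.84 (SE 0.372, adjusted p = 0.000145), 4.36 (SE 0.323, adjusted p = 0.000133), 4.57 (SE 0.316, adjusted p = 0.000101) and 6.26 (SE 0.977, adjusted p = 0.00991).

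Of 23 steroid synthesis genes, 4 were called higher after both siRNAs, 0 lower and 19 were not called, with medians of 0.53 (percentile 99.95) after siNC and 0.42 (percentile 99.7) after siYT. Limma called 5 higher, or 8 higher and 1 lower adjusted over the list alone. Of 22 cAMP and CREB responsive genes, 12 were called higher after both siRNAs, 0 lower and 10 were not called, with medians of 1.59 and 2.15, both at the percentile 100. All 12 calls by limma were higher, and adjusted over the list alone 12 were higher and 1 lower. Examples were the orphan nuclear receptors NR4A3 (5.28 and 5.15) and NR4A2 (4.26 and 5.38) and the phosphodiesterases PDE7B (5.06 and 3.61) and PDE4D (3.97 and 4.02), which break down cyclic AMP. NR4A1 was 1.47 and 2.80 higher. The same list had medians of 0.50 (percentile 99.5) and 0.43 (percentile 98.9) for YAP/TAZ siRNA, with 5 members higher in both media, 0 lower and 17 not called. PPARGC1A, a coactivator of mitochondrial genes, was 3.07 and 3.25 higher with that siRNA, which was the largest mean siRNA difference of the list. Limma called 5 higher for the siRNA, or 6 adjusted over the list alone. Averaged over both media, the siRNA median was 0.37 (percentile 99.0), and it was not called without PPARGC1A (percentile 94.8), without members of other lists (percentile 93.2) or with log2 of the linear value plus 32 (percentile 96.1).

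Several of the 12 genes ranked highest with 8Br-cAMP lay outside steroid synthesis. DIO2, which activates thyroid hormone, was 6.11 and 8.78 higher, and ALPL, the alkaline phosphatase, 6.20 and 5.32 higher. The cytokine IL11 was 5.59 and 5.25 higher, HPD, an enzyme of tyrosine breakdown, 5.09 and 5.24, and the receptor TNFRSF19 4.91 and 4.41. RASD1, a small GTPase, was 6.09 and 4.19 higher, and CHMP1B, a protein of membrane scission, 4.12 and 4.92. Ranked lowest were PTX3, the pentraxin of the cumulus matrix (-3.13 and -2.91), the AP-1 subunit JUN (-2.58 and -2.84), the adhesion molecule VCAM1 (-2.496 and -3.22) and CLDN1, a tight junction protein (-2.49 and -3.08). CBS, which makes cystathionine, differed by -2.46 and -3.02, KLF6, a transcription factor, by -2.46 and -2.54, and E2F7, a repressor of E2F target genes, by -2.55 and -2.30. The other genes of the 12 lowest were CMTM3 (-2.25 and -3.45), CAV1, the coat protein of caveolae (-2.23 and -2.52), EMP1 (-2.52 and -2.20), ULBP1, a ligand of natural killer cells (-2.16 and -2.36), and TMEM171 (-2.79 and -2.12). At least 1 value lay under the level filter in 8 of the 12 highest and 5 of the 12 lowest genes, so their sizes depend on the background.

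Contractile and adhesion genes were lower as a group. Of 22 actomyosin and focal adhesion genes, 7 were called lower after both siRNAs, 0 higher and 15 were not called, with medians of -0.69 and -0.88, both at the percentile 0. ACTA2, smooth muscle actin (-1.59 and -1.90), and the actin-binding proteins CNN1 (-1.87 and -1.61) and TAGLN (-1.29 and -2.15) were examples. Limma called 4 lower, or 12 adjusted over the list alone. For YAP/TAZ siRNA this list was not called, with medians of -0.07 and -0.19, 1 member higher in both media, 3 lower and 18 not called; TAGLN differed by -2.05 and -2.91. Limma called 1 higher and 3 lower for the siRNA, or 2 and 5 adjusted over the list alone. Of 11 housekeeping genes, ACTB, cytoplasmic actin, was called lower with 8Br-cAMP (-1.64 and -1.51), 10 were not called, and the medians were 0.07 and 0.06. Limma and the list alone both gave 1 lower. For the siRNA the housekeeping medians were 0.11 and 0.24, with 0 members called in both media.

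DNA replication and mitosis genes had lower medians with 8Br-cAMP after both siRNAs, and YAP/TAZ targets after siNC, although most members were not called. The YAP/TAZ signature had medians of -0.41 (percentile 0.12) after siNC and -0.23 (percentile 7.24) after siYT, with 4 members lower after both siRNAs, 0 higher and 15 not called. They were ANKRD1 (-1.34 and -4.46), CCN1 (-1.19 and -2.04), CCN2 (-1.21 and -1.54) and MYOF, a membrane repair protein (-1.34 and -1.32). By limma 2 members fell, and adjusted over the list alone 4 fell and 1 rose. Hippo components and TEAD factors had medians of -0.40 (percentile 0.63) and -0.46 (percentile 0.20), and FRMD6, an upstream regulator (-2.502 and -1.86), was the 1 member called, with 19 not called. Limma gave the same count of 1 over all genes and over the list alone. DNA replication genes had medians of -0.92 and -0.65, both at the percentile 0, with 6 members lower, 0 higher and 17 not called. GINS1, a helicase subunit (-2.23 and -1.72), and the cyclin CCNE2 (-1.08 and -2.52) were examples, and limma called 5 lower, or 10 adjusted over the list alone. Mitosis genes had medians of -0.49 (percentile 0.06) and -0.89 (percentile 0), with 2 members lower, AURKB (-1.41 and -1.44) and MKI67 (-1.003 and -1.78), 0 higher and 23 not called. Limma called 1 lower, or 4 adjusted over the list alone.

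Among signalling lists, 21 TGF-beta and BMP genes had medians of 0.91 and 0.74, both at the percentile 100, with 4 members higher after both siRNAs, 0 lower and 17 not called. TGFB3 was 2.89 and 5.92 higher and ID3, an inhibitor of differentiation, 2.89 and 1.14. Both differences of TGFB3 start from values under the level filter, 3.54 in siNC and 4.69 in siYT. Limma called 4 higher, or 10 higher and 2 lower adjusted over the list alone. Granulosa identity genes had medians of 0.39 (percentile 99.2) and 0.24 (percentile 94.7), with 3 higher, 0 lower and 17 not called. Averaged over both siRNAs the median was 0.28 (percentile 98.9), and it was not called for members past the level filter (percentile 96.1) or without members of other lists (percentile 96.7). Limma called 3 higher, or 3 higher and 1 lower adjusted over the list alone. INHBA, an activin subunit, was 2.04 and 3.997 higher and GJA1 2.501 and 1.17. Inflammatory genes had medians of -0.74 and -1.26, both at the percentile 0, although IL11 was higher. Of these, 2 were called higher, 3 lower and 14 not called, and limma called 1 higher and 2 lower, or 3 and 8 adjusted over the list alone. The matrix list had medians of 0.02 and -0.42 (percentile 0.15), with 1 member higher, 2 lower and 21 not called. TNC, tenascin, differed by -1.58 and -3.05 and COL4A1, a basement membrane collagen, by 1.80 and 1.06, and limma called 1 lower, or 1 higher and 3 lower adjusted over the list alone. Apoptosis regulators had medians of -0.31 and -0.41 (percentile 1.49), with BMF (1.24 and 1.18), which promotes cell death, higher, BAX (-1.17 and -1.27), which permeabilises mitochondria, lower and 15 not called. Limma called 0 of them over all genes, and 1 higher and 1 lower adjusted over the list alone. BMF passed the level filter only in siYT+8Br-cAMP, at 6.84. That value lies under the filter set from the negative controls, 6.95, so BMF is not called with that filter.

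Over all genes, 1426 were called after siNC, 764 higher and 662 lower, and 1452 after siYT, 718 higher and 734 lower. This balance depended on scaling, with 675 higher and 750 lower after siNC with cyclic loess, and 795 higher and 654 lower after siYT with centring. After both siRNAs 539 were called in the same direction, 308 higher and 231 lower. Of the 1426 genes, 1182 (82.9%) had the same direction after siYT and 19 were at least 2-fold different the opposite way. Across the same 9752 genes the differences after the 2 siRNAs correlated with r = 0.560 and rho = 0.473. Limma called 321 genes, 204 that rose and 117 that fell. That count was 705 when only genes past the level filter were fitted, 731 after cyclic loess, and 0 with log2 of the linear value plus 32, where 2769 had an unadjusted p under 0.05.

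**Figure D3:**
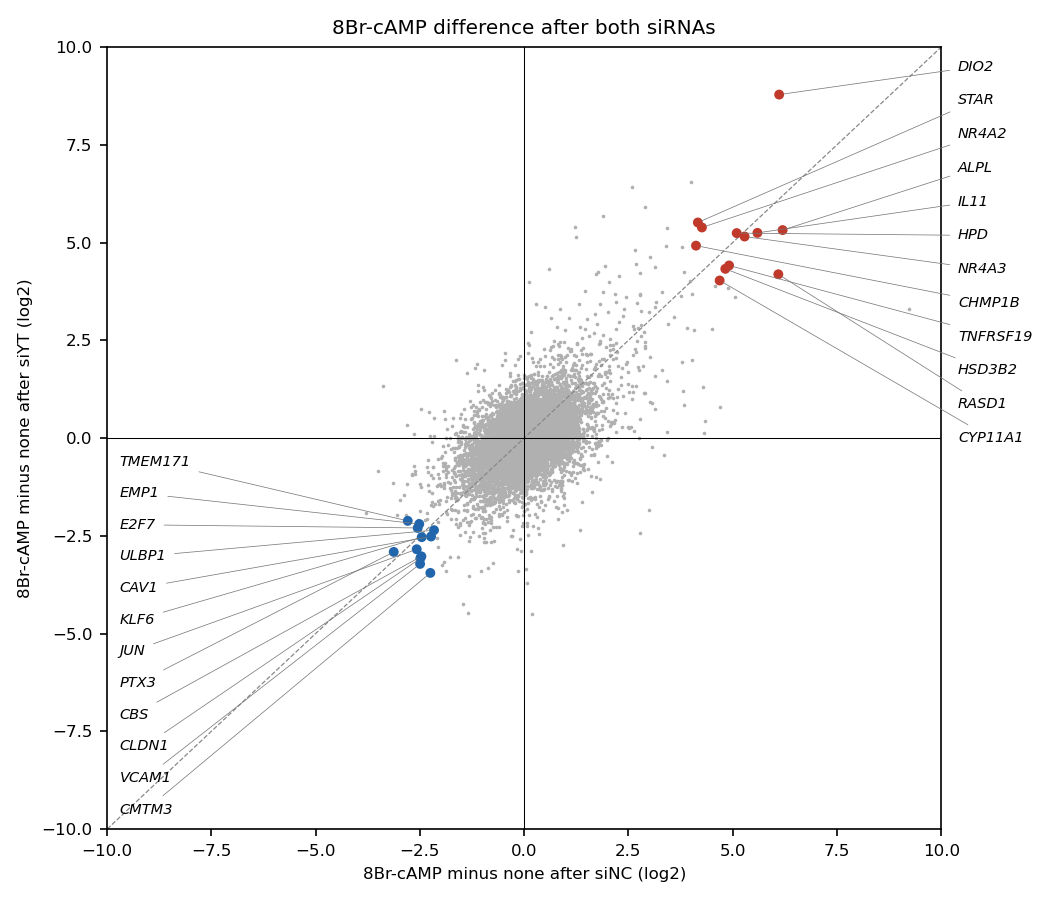
Difference between cells with and without 8Br-cAMP on the log2 scale after siNC (horizontal axis) and after siYT (vertical axis), 1 point per gene past the level filter, with the 12 highest genes by the smaller of both differences in red, the 12 lowest in blue and equality as a dashed line. DIO2 lies at 6.11 and 8.78, and PTX3 at -3.13 and -2.91.

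The same genes were often higher, or lower, with both treatments. Among the 9752 genes, 1015 had a mean siRNA difference of at least 1 and 561 a mean 8Br-cAMP difference of at least 1, and 185 had both, where 58.4 would be shared if the effects were independent. CYP19A1, CYP11A1 and HSD3B2 were among them. In the other direction, 215 genes were lower with both, where 55.0 would be shared. Opposite directions were shared by 35 genes, higher with siRNA and lower with 8Br-cAMP, where 52.4 would be, and by 28 the other way round, where 61.4 would be. Across these genes the 2 mean differences, which are orthogonal contrasts of the 4 arrays, correlated with r = 0.342 and rho = 0.298. Both means take siNC with a minus sign and siYT+8Br-cAMP with a plus sign. A peculiarity of either culture would therefore also raise the number of genes shared in the same direction. With 1 array per group this cannot be told apart from an effect shared by the treatments.

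The third comparison asked which genes responded differently to 8Br-cAMP after YAP/TAZ siRNA. CYP19A1 had the lowest difference of differences, -5.93. Its level was 14.26 with either treatment alone and 17.56 with both, from 5.04 in siNC. That siNC value lies under the level filter, so the size and the rank of CYP19A1 depend on the background. Both single differences, 9.23 each, added to that siNC value would pass 19.36, the highest deposited value. A negative difference of differences was therefore fixed by the range of the values, and it does not show a weaker response. IL6 was 2.78 higher with 8Br-cAMP after siNC and -2.44 different after siYT. TRIB2, a pseudokinase, differed by 2.999 and -1.84. SLC14A1, a urea transporter, differed by 0.19 and -4.49 and EDN2, an endothelin, by 4.31 and 0.12. ID2, an inhibitor of differentiation, differed by 4.70 and 0.79, TNFSF10, the death ligand TRAIL, by 4.33 and 0.44, and SPRY1, an antagonist of receptor kinases, by 3.36 and -0.43. In the other direction ADAMTS1, a protease that cleaves versican at ovulation, was lower after siNC and higher after siYT, with -3.40 and 1.32. The unconventional myosin MYO10 differed by 1.23 and 5.40, RAP1GAP, which inactivates RAP1, by 1.24 and 5.15, and GREB1, an estrogen-induced gene, by 0.12 and 3.98. ACTBL2, an actin-like protein, differed by 2.57 and 6.41, CPM, a carboxypeptidase, by 1.89 and 5.68, KCNJ8, a potassium channel, by 0.59 and 4.32, and SDC1, syndecan 1, by -1.63 and 2.01. Of these 16 genes, 6 of the 8 highest and 4 of the 8 lowest had at least 1 value under the level filter.

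Of all genes, 1484 had a difference of differences of at least 1, 631 higher and 853 lower. This balance turned to 797 higher and 690 lower after centring and to 1409 higher and 1347 lower without a level filter. At 2 or more there were 181 genes, 62 higher and 119 lower, at 3 or more 32, and at 4 or more 7. With 1 array per group, noise of the arrays was not separated from these differences. The mean difference of the siRNA split reached 1 in 2082 genes and that of the medium split in 1064. The crossed split, siNC and siYT+8Br-cAMP against the other pair of arrays, is the difference of differences divided by 2, so it gave the same 181 genes and is no separate measure of noise.

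Gene lists differed as well in their 8Br-cAMP response. The 23 interferon response genes had a median 8Br-cAMP difference of 0.18 (percentile 81.1) after siNC and -1.07 (percentile 0) after siYT, with 12 members called lower, 0 higher and 11 not called by the difference of differences. OAS2, an antiviral enzyme, differed by 0.80 and -2.08, OAS1 by 0.41 and -1.60 and IFIT1 by 0.06 and -1.82. The median difference of differences was -1.16, at the percentile 0. After both siRNAs 1 member was called lower with 8Br-cAMP, IFIT2 (-1.23 and -2.41), and 22 were not called; limma also called 1, or 2 lower adjusted over the list alone. CDK inhibitors and p53 targets had a median difference of differences of -0.67 (percentile 0.04), with medians of 0.15 after siNC and -0.57 (percentile 0.09) after siYT. SESN1, a p53 target, differed by 1.26 and -1.14. With 8Br-cAMP 1 member was higher after both siRNAs, the secreted factor GDF15 (2.63 and 2.80), 2 were lower and 14 were not called, and limma called 1 higher and 1 lower, or 1 and 2 adjusted over the list alone. For the siRNA, limma and the list alone gave 1 higher. Steroid synthesis genes had a median difference of differences of -0.43 (percentile 0.65), or -0.31 (percentile 3.33) without CYP19A1 and -0.07 (percentile 32.1) with log2 of the linear value plus 32, and was called under neither. TGF-beta and BMP genes were at -0.53 (percentile 0.18) and the cAMP and CREB genes at 0.35 (percentile 98.5). The latter were not called after cyclic loess (0.297, percentile 96.1) or by their mean (0.226, percentile 94.2). SGK1, a kinase of that list, was 1.72 higher after siNC and 4.18 higher after siYT. The matrix list was at -0.33 (percentile 2.25), or -0.31 (percentile 3.56) without its member with the largest difference, and was not called in 4 of the alternatives. Each of these differences rests on the same 4 arrays, 1 per group.

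**Figure D4:**
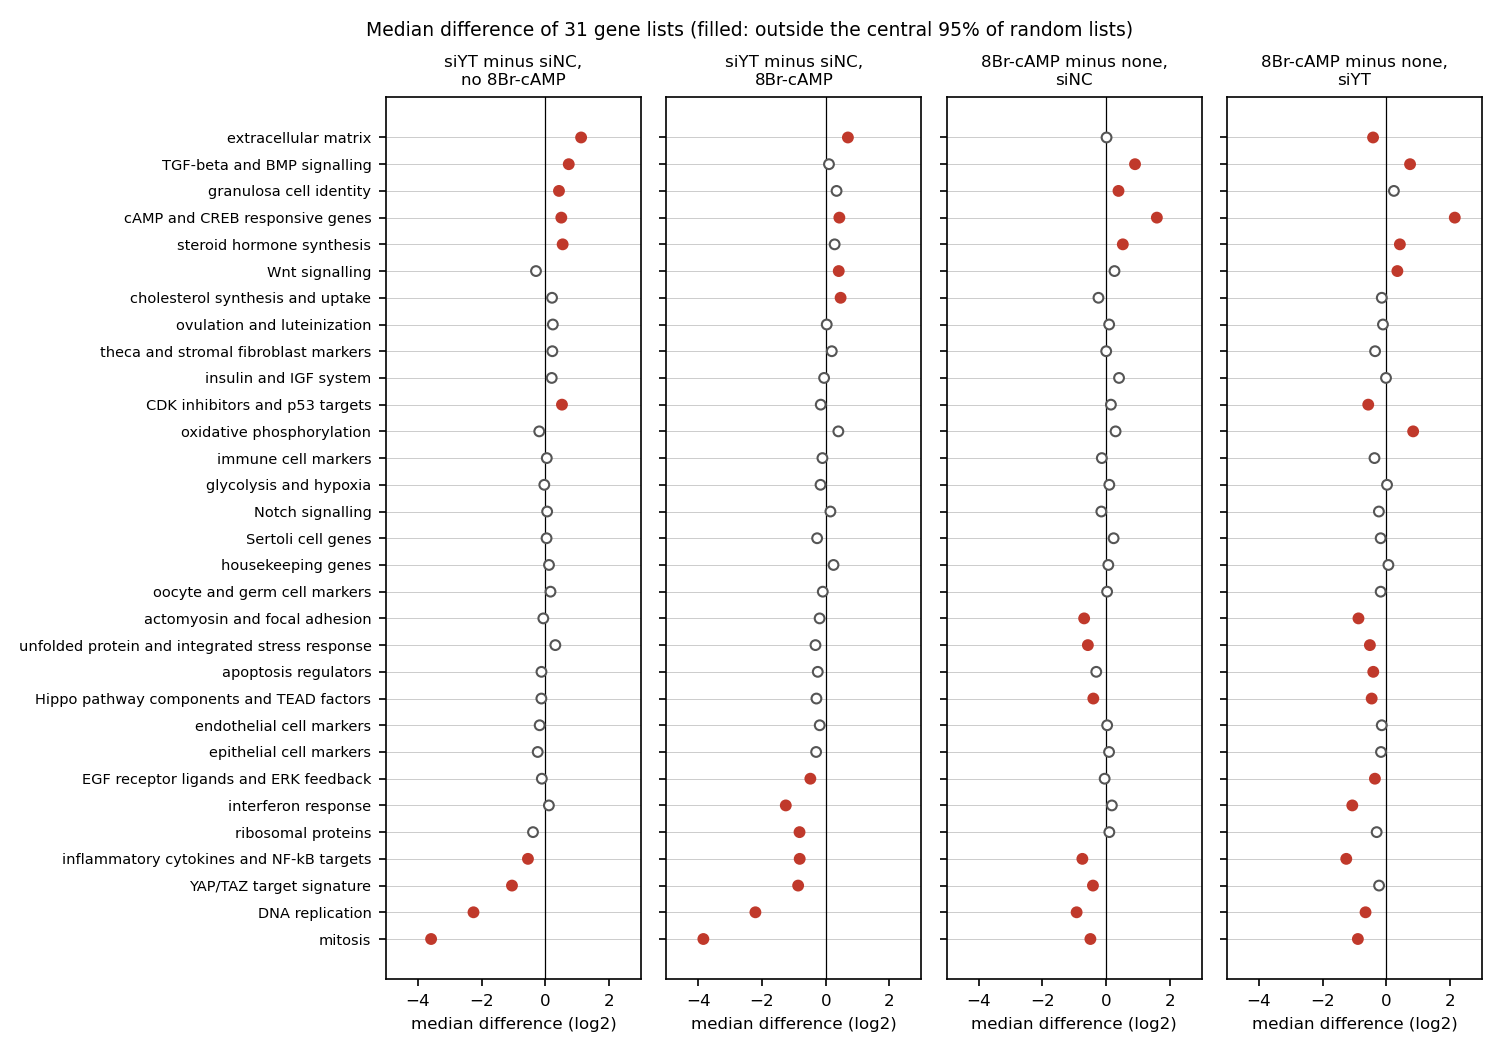
Median log2 difference (horizontal axes) of 31 gene lists, sorted by their siRNA difference, for siYT minus siNC without and with 8Br-cAMP and for 8Br-cAMP minus none after siNC and siYT, with filled points for lists outside the central 95% of random lists. Mitosis genes lie at -3.59 and -3.84 for the siRNA, and cAMP and CREB responsive genes at 1.59 and 2.15 for 8Br-cAMP.

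Genes of ovulation and luteinization went both ways. Their medians were 0.23 and 0.03 for the siRNA, where the means were -0.15 and -0.01, and 0.10 and -0.11 for 8Br-cAMP, and none of these medians was called. Averaged over both media, the siRNA median without the member with the largest difference was 0.38 (percentile 98.6) and called. Averaged over both siRNAs, the 8Br-cAMP mean over members was 0.31 (percentile 97.97) and called. With 8Br-cAMP, STAR and HAS2, the hyaluronan synthase of the cumulus matrix (2.02 and 3.23), were among 3 members of 20 called higher after both siRNAs, PTX3 was the 1 called lower and 16 were not called. With the siRNA, PTX3 (-4.18 and -3.96) was the 1 member called in both media and 19 were not called. Limma called 1 higher and 3 lower for the siRNA and 3 higher and 1 lower for 8Br-cAMP; adjusted over the list alone it called 5 higher and 4 lower for each. PTGS2, the prostaglandin synthase, differed by 0.83 and 2.92 with the siRNA.

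Marker lists of other cell types were mostly near the background. None of the 8 oocyte and germ cell markers passed the level filter, and none was called. Of 8 endothelial markers 2 passed the filter and none was called in both cases, with medians between -0.19 and 0.03; limma called 1 lower with the siRNA, over all genes and over the list alone. TEK, an angiopoietin receptor, differed by -1.35 and -1.70 with the siRNA. Of 7 immune markers, CD68, a lysosomal protein, was 1.92 and 2.82 higher with the siRNA, the 1 member called by size and by limma, also over the list alone, and 6 were not called. Of 10 epithelial markers, KRT18 was the 1 member called lower with the siRNA by size and by limma, also over the list alone, and 9 were not called. Of 11 Sertoli cell genes, CLDN11, a tight junction protein, was lower (-3.10 and -2.92) and TSPAN8, a tetraspanin, higher (2.75 and 1.82) with the siRNA, with 9 not called. The same 2 genes were called with 8Br-cAMP (-1.32 and -1.15, and 3.01 and 2.07). For Sertoli genes limma called 1 higher and 1 lower with the siRNA and 1 higher with 8Br-cAMP; adjusted over the list alone these became 1 higher and 2 lower, and 1 higher and 1 lower. No list of this paragraph was called by its median. For the siRNA difference averaged over both media, the mean over the epithelial markers was -0.60 (percentile 0.49), so that list was called by its mean.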

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

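The tests of fibroblast RNA and of array scaling were chosen after the result was seen; the other tests were written before. The paired differences named first were singled out because they lay at least 2-fold in opposite directions, and with 1 array per group these differences of differences were not tested.

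With 8Br-cAMP, ADAMTS1 differed by -3.40 after siNC and 1.32 after siYT, a difference of differences of 4.72. SDC1 differed by -1.63 and 2.01, giving 3.64. IL6 differed by 2.78 and -2.44, giving -5.215, and TRIB2 by 2.999 and -1.84, giving -4.84. With YAP/TAZ siRNA, TRIB2 differed by 3.66 without and -1.18 with 8Br-cAMP, giving the same -4.84. DIO2 differed by -1.63 and 1.039, giving 2.67, MYO10 by -1.79 and 2.38, giving 4.18, and CPM by -1.93 and 1.86, giving 3.79. Outside the gene-named data, 65 of the 3739 transcript clusters without a named gene were called higher in both media with YAP/TAZ siRNA and 70 lower, and 33 were called higher with 8Br-cAMP after both siRNAs and 22 lower. The 4 hybridisation controls, which are added to every array, had a median mean difference of 0.322 with 8Br-cAMP, 0.441 after siNC and 0.18 after siYT.

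The 23 interferon response genes had a median 8Br-cAMP difference of 0.18 after siNC and -1.07 after siYT. The 20 members with a mean at or above the level filter had a median difference of differences of -1.23. Its 95% bootstrap interval ran from -1.63 to -0.82. The pattern was therefore not limited to dim probe sets, but a median over 20 of 23 members was bound to lie near that of the list. Without the 2 lowest members the median was -0.98, from -1.28 to -0.67. With 12 of 23 members called lower, the median depended little on any 2 members, so this result was nearly fixed in advance. Both intervals resample members measured on the same 4 arrays and do not measure the spread between cultures. The list stayed at the percentile 0 after cyclic loess. Loess shifted the array medians by at most 0.032, so this was all but fixed in advance and says little about scaling between arrays. An interaction of YAP/TAZ loss with cyclic AMP and a peculiarity of the siYT+8Br-cAMP culture could each give these values, and both stay open because 1 culture decides the pattern.

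LUM, DCN, MGP, HMCN1 and C7, genes that stromal cells express, were higher after YAP/TAZ siRNA, with a median mean difference of 4.895. Of these, C7 stayed under the filter set from the negative controls, 6.95, on every array and is not called with it. Fibroblast RNA in the siYT cultures would bring other stromal transcripts. The 7 other matrix and stromal genes fixed beforehand that lay under the level filter in siNC, CYP17A1, INSL3, TCF21, COL6A3, POSTN, ELN and FBLN1, had a median of 0.14, from 0.05 to 0.22. They stayed under the filter on all 4 arrays, and CYP17A1 and INSL3 mark theca rather than fibroblasts, so this median excludes nothing. COL1A1, a collagen of fibroblasts that was already high in siNC, differed by 0.11 without and -0.99 with 8Br-cAMP. The stromal markers PDGFRA (2.54 and 0.06) and PDGFRB (1.87 and 0.47) were higher without 8Br-cAMP and not called with it. After cyclic loess the 5 genes had a median of 4.883, which is 0.998 of that in the deposited values. Loess shifted the array medians by at most 0.032, so a ratio near 1 was all but fixed in advance. A shift of that size could not give 4.895, and other kinds of scaling were not tested. Fibroblast RNA in the siYT cultures and a response of the KGN cells both stay open, since no test here decides between them, and an effect of the siRNAs on other targets was not tested.

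Genes called higher both with YAP/TAZ siRNA without 8Br-cAMP and with 8Br-cAMP after siNC, 344 in all, had a median difference of differences of -0.94, so that their response to 8Br-cAMP looked smaller after siYT. These calls share the siNC array, and 24 genes called in this way in simulated arrays without any effect had a median of -1.59. Picked by the mean of each effect, which is orthogonal to the difference of differences, 185 genes had a median of -0.17, from -0.34 to -0.0049. Among these, the 110 with a siYT+8Br-cAMP value under 12 had a median of -0.065, from -0.25 to 0.09, and the 75 at 12 or more had -0.34, from -0.52 to -0.08. The 185 genes are another set than the 344. They include genes such as GREB1, which differed little with the siRNA alone (0.43) or 8Br-cAMP alone (0.12). Selection on the shared array and compression at high values can each contribute, but these values do not decide how much of the pattern they account for.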

How the results depend on the processing

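The filter at the 95th percentile of the negative controls was chosen after the data were seen. Of 84 counts under alternatives, 55 stayed within 1.5 times and 29 did not. The order is siRNA without and with 8Br-cAMP, 8Br-cAMP after siNC and after siYT, then the difference of differences and the crossed split. At 1.5-fold these counts were 4680, 4124, 3517, 3418, 3728 and 991, and at 3-fold 1162, 778, 411, 459, 397 and 24. A filter at the 75th percentile gave 1637, 1185, 845, 828, 724 and 101. These follow from the settings themselves. Both media shared 2693 genes at 1.5-fold and 513 at 3-fold, and both siRNAs 1594 and 167. Without a filter 2756 genes had a different response. For the crossed split, log2 of the linear value plus 32 gave 104. With that setting limma called 0 genes for the siRNA (3964 at an unadjusted p under 0.05) and 0 for 8Br-cAMP (2769), while sizes still called genes. For 8Br-cAMP, limma called 705 genes among those past the filter, where fewer were tested, 731 after cyclic loess and 489 after centring; otherwise the cause was not tested. Centring moved the median of all genes in the siRNA difference with 8Br-cAMP from 0.06 to 0.11, and raised the share of higher genes among different responses from 42.5% to 53.6%.

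Lists were repeated for the siRNA difference averaged over both media, the 8Br-cAMP difference averaged over both siRNAs and the difference of differences, and not for each medium or siRNA. Of 597 list values under alternatives, of which 93 are means and the others medians, 545 kept their side of the call, 34 gained it, 18 lost it and 0 reversed. The cAMP and CREB genes lost their siRNA call without PPARGC1A (percentile 94.8), and the granulosa genes theirs without CYP19A1 (percentile 97.4). Of 1688 values of named genes, 1640 were kept, 12 gained and 36 lost a call and 0 reversed, 32 of the 36 with log2 of the linear value plus 32. Signal near the background limits genes such as FSHR, whose siYT values lay close to the filter.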

Other observations

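Genes of the unfolded protein and integrated stress response had a lower median with 8Br-cAMP, and the list was not called by its median with YAP/TAZ siRNA. Of the 19 genes, 6 were called lower with 8Br-cAMP after both siRNAs, 0 higher and 13 not called, with medians of -0.57 (percentile 0.01) after siNC and -0.52 (percentile 0.21) after siYT. By single comparison, 4 were called higher and 6 lower after siNC, and 0 higher and 9 lower after siYT. The median difference of differences was -0.86 (percentile 0), with 1 member called higher and 6 lower. With YAP/TAZ siRNA 5 were called lower in both media, 0 higher and 14 not called, with medians of 0.31 (percentile 85.9) and -0.32 (percentile 5.83). Without 8Br-cAMP 5 were called higher and 6 lower with the siRNA. Averaged over both media, the siRNA median was -0.11 (percentile 23.8), and the mean over members of -0.41 (percentile 2.48) was called. ASNS, which makes asparagine, differed by -1.33 and -3.54 with 8Br-cAMP and by -1.84 and -4.05 with the siRNA. PSAT1, of serine synthesis, differed by -1.93 and -3.17 and by -2.05 and -3.29, and CHAC1, which degrades glutathione, by -3.80 and -1.91 and by -3.45 and -1.56. DDIT3, the stress factor CHOP, was lower with 8Br-cAMP, by -1.88 and -3.41. Limma called 5 lower with each treatment, and adjusted over the list alone 3 higher and 5 lower with the siRNA and 2 higher and 8 lower with 8Br-cAMP.

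Of 18 oxidative phosphorylation genes, 0 were called with 8Br-cAMP after siNC and 8 higher after siYT, with medians of 0.30 (percentile 85.6) and 0.84 (percentile 99.99). The median difference of differences was 0.59 (percentile 100). ATP5MC1, a subunit of ATP synthase, differed by 0.39 and 1.83, and CYCS, cytochrome c, by 0.16 and 1.55. Limma called 0 of these genes over all genes and over the list alone. Among 19 glycolysis and hypoxia genes, 0 were called after both siRNAs and the medians were 0.10 and 0.02, but 6 were called lower by the difference of differences. ADM, the peptide adrenomedullin, differed by 0.05 and -3.36 with 8Br-cAMP, SLC2A1, the glucose transporter GLUT1, by 0.07 and -2.26 and NDRG1 by 1.82 and -1.06. ADM was the 1 member called lower in both media with the siRNA (-1.45 and -4.85), and limma called 2 lower, also over the list alone. Of 16 insulin and IGF genes, 5 were called higher with 8Br-cAMP after both siRNAs, 0 lower and 11 not called, with medians of 0.41 (percentile 97.3) and -0.01. IGFBP4, which binds IGF (3.82 and 4.25), PAPPA, the protease that cleaves IGFBP4 (2.06 and 1.66), and STC1, an inhibitor of PAPPA (2.68 and 1.34), were higher together. Its relative STC2 was lower with the siRNA (-2.85 and -2.92), as was IGFBP3 (-1.05 and -2.86), and the other 14 were not called. Limma called 4 higher with 8Br-cAMP, or 5 higher and 1 lower adjusted over the list alone, and 2 lower with the siRNA, or 3 over the list alone.

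Among 18 Wnt genes, 3 were called higher with 8Br-cAMP after both siRNAs, 0 lower and 15 not called, with medians of 0.26 (percentile 95.7) and 0.35 (percentile 98.9). The secreted antagonist SFRP1 was 2.28 and 4.13 higher, the feedback target AXIN2 2.34 and 1.79, and CTNNB1, beta-catenin, 1.19 and 2.12. With the siRNA, SFRP4 (3.002 and 1.60) and AXIN2 (1.76 and 1.21) were higher, DKK1 (-1.16 and -2.79) was lower and 15 were not called, with medians of -0.30 and 0.41 (percentile 97.7). AXIN2 passed the level filter only in siYT+8Br-cAMP, at 7.39, and was at 3.84 in siNC. Its sizes for both treatments therefore depend on the background. Limma called 2 higher and 1 lower with the siRNA, or 2 and 2 over the list alone, and 3 higher with 8Br-cAMP, or 4. Of 13 Notch genes, HEY1 (1.26 and 1.90) and HES1 (1.06 and 1.24), targets of the pathway, were called higher with the siRNA in both media, the ligand JAG1 (-1.04 and -1.14) lower and 10 were not called. The Notch medians of 0.05 and 0.15 were not called, limma called 2 higher, or 2 higher and 1 lower over the list alone, and none was called with 8Br-cAMP after both siRNAs.

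The 15 ribosomal protein genes named by a probe set of their own had medians of -0.39 (percentile 4.83) and -0.82 (percentile 0.14) with the siRNA, and 0 were called in both media or by limma. RPL10A differed by -0.95 and -0.88. Apoptosis regulators had siRNA medians of -0.12 and -0.25, with BMF (1.47 and 1.41) called higher, PMAIP1, known as NOXA (-1.78 and -1.41), and APAF1, the apoptosome scaffold (-1.12 and -1.65), called lower and 14 not called. BMF stayed under the filter set from the negative controls, 6.95, on every array and is not called with it. Cholesterol genes had 8Br-cAMP medians of -0.24 and -0.14, with LSS, which makes lanosterol, called lower (-1.20 and -1.53) and 18 not called. Of the EGF receptor ligand and ERK feedback genes, FOSL1 was called lower with 8Br-cAMP (-3.04 and -1.97) and 20 were not called, with medians of -0.04 and -0.36 (percentile 1.68).

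Median and mean differed in sign for some of these lists. The stress response list had a mean of -0.11 with the siRNA without 8Br-cAMP and the Wnt list of 0.04. After siYT, the 8Br-cAMP mean was -0.48 for the glycolysis list and 0.40 for the insulin and IGF list. The ovulation, Sertoli, Notch, housekeeping, immune, endothelial and oocyte lists also had at least 1 median with a sign opposite to its mean.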
